A study of Rattus norvegicus with 2 samples.

How the data were processed

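Gene expression was measured in single cells of the zygomatic maxillary suture, the fibrous joint between the cheek bone and the upper jaw, of 4-week-old rats. The distraction group carried a spring of 0.4 mm nickel-titanium wire with an initial force of 20 g that pulled the suture apart for 7 days, and the sham group had the holes drilled without the spring. Each group has 1 library, and the number of animals behind a library is not given in the sources used here. Per the labels' protocols, the tissue was broken up into a cell suspension and single cells were trapped on a BD Rhapsody cartridge, in which each cell lands in a microwell with a barcoded bead.

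The deposited values are whole-number counts of molecules per gene and cell, with no scaling. Per the file headers, the authors made these counts with the BD WTA Rhapsody Analysis Pipeline 1.5.1, and the submitters' processing notes name the genome build Rnor_6.0 and Seurat 3.6 without saying what each did. The annotation release and the rule by which barcodes were called cells are not given in the sources used here. The distraction table listed 20560 genes and the sham library 20412, with 18818 in both, and a gene listed in 1 table was counted as 0 in the other. Gene symbols are those of the tables, and no coordinates are given because the gene table at hand belongs to another assembly.

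The distraction table held 4889 cells with 32078960 molecules (UMIs) and the sham library 5351 cells with 29924342. Cells with at least 500 UMIs, at least 200 genes and under 25% mitochondrial UMIs were kept, which left 4037 distraction cells with a median of 4161 UMIs and 5183 sham cells with a median of 3033. The shallowest deposited sham cell had 920 UMIs, and 601 of the deposited distraction cells lay below that, so the libraries differ in how shallow cells entered them. Scrublet, as built into scanpy 1.11.5, was run per library with an expected doublet share of 5% and marked 8 and 3 cells, or 0.119% of 9220. A share so far below the expected 5% was taken to mean that the caller did not work, which was not tested. The marked cells were removed, which left 4029 and 5180 cells, and undetected doublets must be assumed to remain.

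Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1 (leidenalg 0.10.2, igraph 0.11.9) gave 30 clusters over both libraries, without integration. The markers of each cell type were fixed before the data were examined. The scoring rule was set after the clusters had been seen: a marker counted when at least 10% of a cluster's cells held it at no less than 2 times the level of the median cluster, and a name needed 3 such markers and a score of 0.25. Clusters led by another class's genes, and clusters with class II genes as their only dendritic markers, stayed unnamed. All unnamed clusters together, including those short of markers or score, held 5.98% of distraction and 5.14% of sham cells. A name ending in "-like" rests on these markers alone.

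With 1 library per group there is no replicate spread, so no test between the groups was made and no p-value is given. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Genes within a class were compared as the ratio of summed counts scaled to the same total per class and library (CPM, counts per 1e6), with exact 95% intervals from the conditional binomial of 2 Poisson counts. All intervals cover counting error only, not differences between animals, dissections or cells. A gene was called higher or lower when its ratio reached 1.5 and its interval lay on 1 side of 1. Against a count of 0, the fold is a lower bound computed with a floor of 3 counts over the library's class. Classes needed 50 cells in both libraries for named genes, and smaller classes have list results alone. The fibroblast-like class, which the series title asks about, has 33 sham cells and was reported all the same, an exception to that minimum.

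Genes were named by a rule of size fixed before the data were examined. Candidates had at least 50 CPM in 1 library, 30 counts over both and a symbol, were not mitochondrial, ribosomal protein, haemoglobin or immunoglobulin genes or markers of the class, and reached at least 10% of the level of the class that expressed them most, to set aside possible free RNA. Ranked by the log2 ratio with a pseudocount of 1 CPM, up to 12 highest and 12 lowest were named in fibroblast-like cells, 5 and 5 in neutrophil-like and monocyte-like cells and 3 and 3 elsewhere. Of each gene list, up to 4 members with the largest ratio at 50 CPM or more could be named, and Cdh5, Kdr, Flt1, Tek, Vwf, Eng and Vegfa were named in fibroblast-like cells whatever their values. Pecam1, also fixed for that purpose, was not analysed here. Other genes named in the text were chosen after their values were seen. The pattern that left out haemoglobin genes also took out Hbegf at an early stage and was corrected after results had been seen.

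The gene lists, also fixed before the data were examined, cover endothelial identity, angiogenic ligands and modulators, tip cells and activated endothelium, collagens and matrix, collagen processing, matrix degradation, osteogenic genes, suture progenitors, tendon and ligament, YAP/TAZ targets, contractile and myofibroblast genes, TGF-beta, hypoxia and glycolysis, oxidative phosphorylation, proliferation, immediate early and stress genes, inflammatory cytokines and chemokines, interferon response, class II antigen presentation, tissue repair macrophages, osteoclasts, neutrophil granules, Wnt, BMP and growth factors, and red cell genes. Members with at least 10 CPM in either library entered, without the class's own markers. Each list has a median log2 ratio with an interval from 1000 Poisson draws, and the percentile of that median among 10000 random lists of the same size matched on expression, as a description of these libraries. The percentiles are not given below, so the medians stand without that comparison. In fibroblast-like cells 10 CPM is fewer counts in the sham library (266810 UMIs) than in the distraction library (884098 UMIs). What this does to the list medians was not tested. To compare shares of cells with endothelial markers, each cell was thinned to 4000 UMIs, which at least 75% of fibroblast-like cells reached, and shallower cells were left out. Fibroblast-like cells were clustered again within the class at resolution 0.5.

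Alternatives fixed beforehand covered the cell filter, doublet handling, clustering resolution, centring or separate clustering of the libraries, denominators, scaling, thinning, the pseudocount and the list minimum. Removal of the highest 2.5% of doublet scores, a UMI minimum of 920 in both libraries, removal of each gene's highest cell, and fibroblast-like cells without a mural-like sub-cluster or without mixed cells were added after the data had been seen. A mixed cell held at least 3 markers of another class at 2 or more UMIs each. Endothelial markers were taken out of that definition after a first look, because they are what was being measured.

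The gene comparison was tested on simulated counts with 200 planted genes. With the fibroblast-like class as the model, 78% of genes planted at 2-fold and 100% at 4-fold were called in the right direction over 2869 genes, 2.29% of unchanged genes were called, and 96.1% of intervals held the true ratio. With the neutrophil-like class as the model, the planted genes were called in 100% of cases at both sizes over 2132 genes, 0% of unchanged genes were called, and 95.1% of intervals held the truth. The simulation has Poisson noise alone and no variation from cell to cell. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used.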

Results

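The data are 2 single-cell libraries of the rat zygomatic maxillary suture, 1 after 7 days of distraction and 1 after a sham operation. The series title asks whether fibroblasts of the suture take on functions of vascular endothelium under mechanical strain. After filtering, the distraction library held 4029 cells with 31123777 UMIs (median 4151 per cell) and the sham library 5180 cells with 29464978 (median 3033). Each group has 1 library, so no difference below has a replicate check, and every interval is a 95% interval for counting error only.

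Most cells of both libraries were of blood and marrow types, and their make-up differed. B-like cells, with the pre-B genes Igll1 and Vpreb1 and the B-cell transcription factor gene Ebf1 among their markers, made up 36.8% of the distraction library (1483 cells, interval 35.3 to 38.3) and 63.7% of the sham library (3300 cells, 62.4 to 65.0), a ratio of 0.578 (0.543 to 0.614). Neutrophil-like cells were at 29.6% (1191 cells) against 14.0% (725 cells), a ratio of 2.11 (1.92 to 2.32). Erythroid-like cells stood at 10.5% against 6.33% (ratio 1.67, 1.44 to 1.93), monocyte-like cells at 5.88% against 3.96% (1.49, 1.23 to 1.80) and granulocyte progenitor-like cells at 4.64% against 2.86% (1.62, 1.30 to 2.03). With every deposited cell kept the monocyte-like ratio was 1.11 and the progenitor-like ratio 1.27. The B-like shares themselves depended on naming. They were 30.6% of distraction and 49.6% of sham cells with called doublets kept, where 248 and 729 of the B-like cells stayed unnamed. With at least 1500 UMIs they were 29.2% and 48.8%.

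Among cells other than B-like, the neutrophil-like ratio was 1.21 (1.11 to 1.33) and the erythroid-like ratio 0.957 (0.826 to 1.11). These depended on the setting: with every deposited cell kept they were 0.991 (0.903 to 1.09) and 0.796, and with called doublets kept, where more B-like cells stayed unnamed, 1.54 and 1.20. Summed over all cells, with no clustering, 8 of 8 B markers were lower in the distraction library (median ratio 0.480), among them Fcrla at 0.441 and Cd79b, a part of the B-cell receptor, at 0.520. All 10 neutrophil markers above the minimum were higher (median 1.65), among them the calprotectin genes S100a8 at 1.93 and S100a9 at 2.03, and 7 of 7 erythroid markers were higher (1.28). The B-like ratio turned to 1.58 when each library was clustered on its own, because 2070 of the 3300 sham B-like cells then fell in clusters left unnamed, 2 of them B by score but with a leading gene of plasma cells, against 1 of 1483 distraction cells.

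Stromal cells were rare, with 111 in the distraction library and 76 in the sham library. Fibroblast-like cells, named from Dcn, Lum, Pdgfra, Dpt, Mfap5 and Fbln1, made up 1.86% of distraction cells (75 cells, 1.47 to 2.33) and 0.637% of sham cells (33 cells, 0.439 to 0.894), a ratio of 2.92 (1.92 to 4.54). Over all cells, with no clustering, 4 of 7 fibroblast markers were higher and 1 lower, with a median ratio of 1.31, from Dcn, at 45.6 against 57.1 CPM, to Dpt at a ratio of 9.44. Osteoblast-like cells were at 0.323% (13 cells) and 0.502% (26 cells), a ratio of 0.643 (0.303 to 1.30), and among stromal cells at 11.7% against 34.2% (ratio 0.342, 0.162 to 0.691). Over all cells 4 of 8 osteoblast markers were lower and 2 higher, with a median ratio of 0.558. The bone matrix genes Ibsp and Bglap had ratios of 0.242 and 0.445 and the osteocyte genes Dmp1 and Phex 0.0476 and 0.0725, while Alpl, the alkaline phosphatase of mineralising cells, was at 1.88 and Runx2, the osteoblast transcription factor gene, at 1.26 (1.12 to 1.41). These sums run over all classes and do not show which of them held the Alpl and Runx2 counts. Within fibroblast-like cells, Alpl was a leading gene of the part with neutrophil genes described below. Endothelial-like cells were at 0.571% (23 cells) against 0.328% (17 cells), a ratio of 1.74 (0.889 to 3.47). The fibroblast-like ratio was 1.53 with every deposited cell kept and 1.56 among stromal cells, and when each library was clustered on its own fibroblast-like cells were not separated from other stromal cells. In that setting 1 distraction cluster of 110 cells with fibroblast markers stayed unnamed, and a sham cluster of 49 cells named endothelial-like was led by matrix genes such as Col3a1 and Postn.

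**Figure D1:**
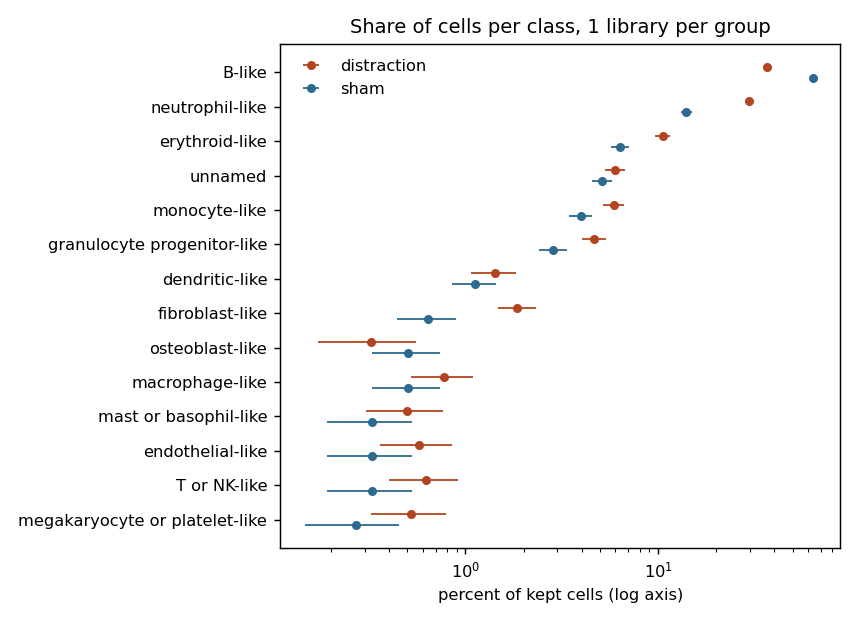
Percent of kept cells in each class (horizontal log axis) in the distraction and the sham library, with exact 95% binomial intervals for counting error. B-like cells stood at 36.8% against 63.7%, neutrophil-like cells at 29.6% against 14.0% and fibroblast-like cells at 1.86% against 0.637%.

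Within fibroblast-like cells, of 24 measured genes for collagens and matrix, 11 were higher and 2 lower, with a median log2 ratio of 0.48 (0.34 to 0.61). Eln, which codes for elastin, was at 281 against 71.2 CPM (3.94-fold, 2.47 to 6.65), Col1a2, a chain of type I collagen, was 2.99-fold higher (1.61 to 6.17) and Thbs2, a matricellular thrombospondin, 2.66-fold higher (2.22 to 3.21). Col8a1 was 11.7-fold lower (7.27 to 19.4). These 4 calls held in all 11 settings that gave counts, with log2 ratios of 1.06 for Col1a2 and 0.69 for Thbs2 without mural-like and mixed cells and -1.90 for Col8a1 without its highest cell, but once mural-like and mixed cells were left out 3 of the 24 were higher and 3 lower (median -0.08). Col1a2 was found in 41 of 75 distraction cells and 7 of 33 sham cells. Col1a1, the other chain of type I collagen, was far more abundant and differed less, at 45514 against 29879 CPM. The Col1a2 ratio is therefore no measure of type I collagen as a whole.

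Among the genes named by size, Cemip, which codes for a hyaluronan-degrading protein, was found in 15 of 75 distraction cells and in no sham cell (105 counts against 0, at least 10.6-fold higher, exact lower bound 8.44). Il1rl1, the IL-33 receptor gene, was at least 5.63-fold higher (56 counts against 0, exact lower bound 4.43). The stromelysin gene Mmp3 was at 222 against 7.50 CPM (29.6-fold, 8.08 to 246), the secreted C1q/TNF-family gene C1qtnf3 at 226 against 11.2 CPM (20.1-fold, 6.79 to 98.4) and Rrad, a small GTPase gene, at 379 against 22.5 CPM (16.8-fold, 7.66 to 46.2). On the lower side, the chemokine gene Cxcl14 was at 20.4 against 731 CPM (35.9-fold, 22.1 to 61.8). These 6 kept their call in all 11 settings, with Cxcl14 at 4.83-fold, C1qtnf3 at 11.8-fold and Mmp3 at 6.49-fold once mural-like and mixed cells were left out. The settings overlap and are not separate checks. Called doublets kept, resolution 2 and at least 1500 UMIs left 62 and 20, 62 and 20, and 61 and 19 cells. Those numbers are near the 64 and 21 cells without the mural-like sub-cluster. Some other settings change only the total used for scaling. Over all settings the log2 ratio of Cxcl14 in fibroblast-like cells ran from -5.42 to -1.81, the log2 ratio of C1qtnf3 in fibroblast-like cells from 3.22 to 7.62 and that of Mmp3 from 2.63 to 6.86. The values rest on few cells: 48.0% of the Mmp3 counts and 51.8% of the Il1rl1 counts came from 1 distraction cell each, and 63.1% of the Cxcl14 counts from 1 sham cell.

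Most other named genes rested on mixed cells or on single cells. The decoy IL-1 receptor gene Il1r2 (at least 15.4-fold higher, exact lower bound 12.4) and Lilrb4 (at least 7.65-fold, exact lower bound 6.07), both also used by myeloid cells, and Pmaip1 (13.9-fold), Glrx (7.59-fold) and Cxcl2 (11.5-fold) were not called once mural-like and mixed cells were left out. Ccnyl1, found in 26 of 75 distraction cells and 1 of 33 sham cells, was 15.7-fold higher (2.70 to 632) and kept its call in 10 of 11 settings, without mural-like and mixed cells among them. By contrast, 94.5% of the counts of Tnfsf18 (7.34-fold) came from 1 distraction cell. On the lower side, the platelet genes Pf4 (98.2-fold), Treml1 (331-fold, 58.1 to 13217), Itga2b (172-fold, 29.6 to 6935) and Ppbp (at least 34.2-fold, exact lower bound 26.2) had all their sham counts in 1 cell. Likewise 1 sham cell held 99.1% of Pla2g2a (75.5-fold), 93.3% of Parvb (33.1-fold, 10.3 to 170), 94.4% of Slc20a2 (25.6-fold) and 95.5% of Wif1 (20.2-fold). Lepr, the leptin receptor gene that marks stromal cells around vessels, was 22.5-fold lower with 94.1% of its sham counts in the mural-like sub-cluster, and Matn4 was 25.4-fold lower with 54.3% of its sham counts in 1 cell. Without mural-like and mixed cells Matn4 had 3 counts against 0 and was not called.

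Clustered again, the class fell into 3 parts. The mural-like part, led by the pericyte genes Rgs5 and Abcc9, held 11 of 75 distraction cells (14.7%) and 12 of 33 sham cells (36.4%). A part led by Nov and Tnfaip6 held 34 and 11 cells, and a part led by Alpl, Bglap and neutrophil genes such as S100a8 held 30 and 10. By their markers, 17 distraction and 5 sham cells were mixed, 15 and 4 of them with neutrophil markers. Removal of both kinds left 47 and 18 cells.

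Osteogenic genes were lower in the distraction library: 10 of 14 were lower and 1 higher, with a median of -1.44 (-1.70 to -1.23). Ibsp was 10.6-fold lower (6.33 to 18.5) and Bglap 4.55-fold lower (3.45 to 6.03), with 68.1% of the distraction and 60.0% of the sham Bglap counts in 1 cell each. Without mural-like and mixed cells 2 of 12 osteogenic genes were lower and 1 higher, and without each gene's highest cell 3 of 12 were lower and 2 higher. Of 13 genes of BMP and growth factor signalling, 9 were lower and none higher (median -1.41, -1.56 to -1.01). They include the secreted BMP antagonists Grem1 (17.3-fold, 9.67 to 33.2) and Nog (4.88-fold, 3.58 to 6.68), the BMP-family gene Gdf10 (17.5-fold, 7.71 to 46.6) and the IGF-binding protein gene Igfbp5 (3.32-fold, 2.82 to 3.92), and all 4 were lower in all 11 settings. Over these settings the log2 ratio of Grem1 in fibroblast-like cells came no nearer 0 than -2.08, with -1.33 for Nog, -2.50 for Gdf10 and -0.69 for Igfbp5. The sham counts lay in few cells: 1 cell each held 69.9% for Grem1, 51.9% for Nog, 43.2% for Gdf10 and 41.8% for Igfbp5. Grem1 was found in 3 of 33 sham cells and 8 of 75 distraction cells. The mural-like sub-cluster held 87.7% of the sham counts of Grem1 and 62.3% of those of Nog. Without mural-like and mixed cells the medians were -0.46 for the osteogenic and -0.62 for the BMP list. Spp1 (4.37-fold lower) turned to higher in that setting, since 97.7% of its sham counts came from 1 cell.

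Neutrophil granule genes were higher in distraction fibroblast-like cells, 6 of 10 with none lower (median 1.97, 1.52 to 2.53), among them S100a9 (8.48-fold) and Cybb, the NADPH oxidase gene of phagocytes (20.4-fold, 5.53 to 170). A single distraction cell held 61.2% of the S100a9 counts, and without mural-like and mixed cells the median was -0.13. Inflammatory genes differed in both directions, with 4 of 17 higher, among them Il1b (99.9-fold, 27.5 to 827) and Ccl3 (12.4-fold), and 6 lower, among them the adhesion gene Vcam1 (8.67-fold, median -0.41). The list's direction turned without the mural-like sub-cluster, with 8 of 16 higher and 0 lower (median 0.98), and with called doublets kept, at resolution 2 and with at least 1500 UMIs, with 7 of 16 higher and 0 lower each. Genes of tissue repair macrophages were 7 lower and 1 higher of 11 (median -2.12), among them Arg1 (66.3-fold, 17.2 to 566) and F13a1 (48.0-fold, 12.2 to 416), and the median was 0.60 without mural-like and mixed cells. Class II genes were 2 higher of 5 (median 1.52), with 88.7% of the distraction Cd74 counts in 1 cell.

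Among matrix-degrading genes 4 of 17 were higher and 7 lower (median 0.04), and beside Mmp3 the collagenase gene Mmp13 was 8.46-fold lower (6.83 to 10.6). Of collagen-processing genes, the cross-linking enzyme genes Lox (1.71-fold) and Loxl2 (1.84-fold) were higher of 15 (median 0.29), though neither was called once mural-like cells and mixed cells were left out. Suture progenitor genes were 2 higher and 5 lower of 14 (median -0.30), among them the niche chemokine gene Cxcl12 (12.6-fold lower), with 96.2% of its sham counts in mural-like cells. Contractile genes were 1 higher and 4 lower of 9 (median -0.51), with the smooth muscle actin gene Acta2 3.59-fold higher (1.94 to 7.38) and Tpm1 4.03-fold lower. The median of the contractile list reversed once mural-like and mixed cells were left out. Targets of YAP and TAZ, the strain-sensitive co-activators, were 0 higher and 3 lower of 17 (median -0.12), with Cyr61 4.17-fold lower (3.35 to 5.20) and Ctgf 3.14-fold lower (2.44 to 4.04). Without mural-like and mixed cells, Cyr61 was at 1.17-fold and Ctgf at 1.78-fold lower, Acta2 was 16.6-fold higher (2.89 to 665), and Mmp13, Vcam1, Ibsp, Tpm1, Il1b, Ccl3, Cybb, S100a9, Arg1 and F13a1 were not called.

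The remaining lists showed smaller medians or few calls. Wnt genes were 3 lower of 10 (median -0.43), interferon response genes 2 lower of 10 (-0.90), TGF-beta genes 1 higher and 1 lower of 12 (0.05) and hypoxia and glycolysis genes 1 higher and 1 lower of 16 (0.13). Oxidative phosphorylation genes were 1 lower of 23 (-0.06), tendon and ligament genes 1 higher of 4 (-0.06), osteoclast genes 1 higher of 5 (0.01) and red cell genes 0 of 3 (0.01). Proliferation genes had a median of 0.77 with 0 of 10 called. Immediate early genes were 4 higher and 3 lower of 16 (median 0.00), with Atf3, a stress-induced transcription factor gene, 2.73-fold higher (2.37 to 3.16) in all 11 settings.

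**Figure D2:**
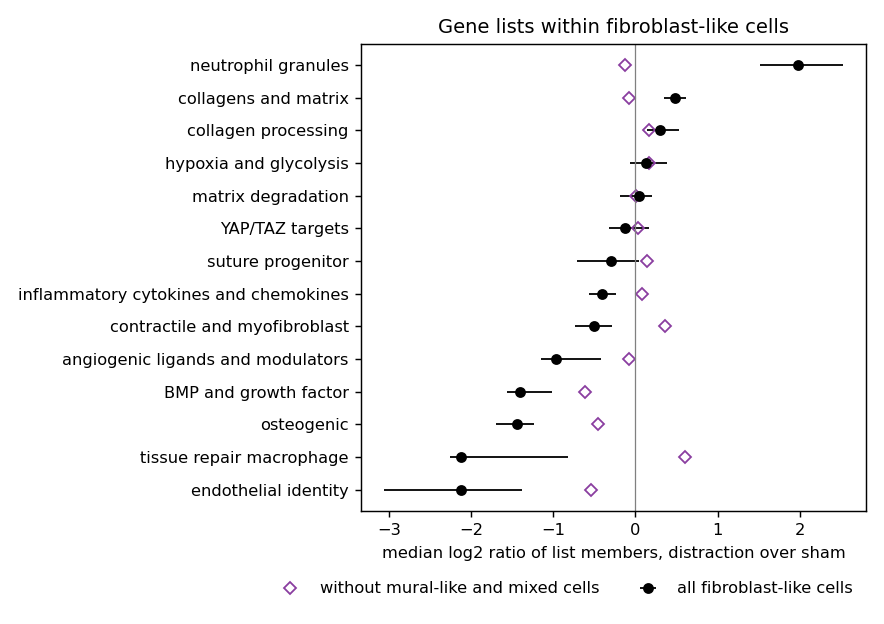
Median log2 ratio of list members (distraction over sham, horizontal axis) in all fibroblast-like cells, with 95% intervals for counting error, beside the median without mural-like and mixed cells (open diamonds). Collagens and matrix went from 0.48 to -0.08, neutrophil granules from 1.97 to -0.13 and endothelial identity from -2.13 to -0.54.

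On the question of the title, genes of endothelial identity were not higher as a group in distraction fibroblast-like cells. Of 12 measured genes 8 were lower and 1 higher, with a median log2 ratio of -2.13 (-3.06 to -1.39). At resolution 2, 2 of 6 were lower and 1 higher, and without mural-like and mixed cells 0 of 4 were lower and 1 higher. Kdr, the main VEGF receptor gene, had 0 counts against 5 (at least 5.52-fold lower by the floor of 3 counts, exact lower bound 3.04), Cdh5, which codes for VE-cadherin, 1 against 7 (23.2-fold lower, 2.98 to 1045), and Vwf 2 against 33 (54.7-fold, 14.0 to 470), with all 33 in 1 sham cell. Flt1 had 10 against 8 counts (2.65-fold lower, 0.909 to 7.46) and Tek 0 against 1. All sham counts of Cdh5 and of Flt1 came from 1 cell each, in the mural-like sub-cluster. Eng, a TGF-beta co-receptor gene also used by stromal cells, was 1.86-fold lower (1.12 to 3.005). Pecam1 was not analysed here. The member that was higher is Erg, an endothelial and chondrocyte transcription factor gene, at 59.9 against 11.2 CPM (5.33-fold, 1.73 to 26.7), found in 24 of 75 distraction cells and 2 of 33 sham cells. After thinning to 4000 UMIs Erg was 2.31-fold higher and was not called.

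After thinning to 4000 UMIs, 3 of 65 distraction fibroblast-like cells (4.62%, 0.962 to 12.9) and 9 of 25 sham cells (36.0%, 18.0 to 57.5) held any of 10 endothelial markers. Without thinning the counts were 9 of 75 and 10 of 33 cells (30.3% in the sham library). Neutrophil-like cells, which should lack these genes, held them at 3.21% and 3.13% with median depths of 4190 and 4250 UMIs, against 9885 and 6743 in fibroblast-like cells, and the distraction share lay near that level. B-like cells held any of the markers at 19.2% and 21.4%, mainly Tie1 (14.2% and 16.1%) and Egfl7 (5.02% and 6.82%), while Cdh5 and Emcn were found in 0 of 578 and 0 of 997 of them. Without mixed cells the shares were 2.08% in the distraction library (1 of 48, 0.0527 to 11.1) and, in the sham library, 5 of 20 (8.66 to 49.1). Without the mural-like sub-cluster they were 3.45% (2 of 58) and 6.25% (1 of 16), and without both 0 of 41 and 0 of 13, with exact upper bounds of 8.60% and 24.7%. All 16 distraction and 12 sham endothelial-like cells held at least 2 of the markers. Of fibroblast-like cells, 1 of 65 in the distraction library (1.54%, 0.0389 to 8.28) and 2 of 25 in the sham library (8%, 0.984 to 26.0) did. The marker found in most sham fibroblast-like cells was Esam, in 5 of 25.

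Angiogenic ligands and modulators were 2 higher and 10 lower of 25 (median -0.97, -1.15 to -0.42). Angptl4 was 15.3-fold lower (11.2 to 21.4) and Adm, the adrenomedullin gene, 6.06-fold lower (4.20 to 8.85), while the semaphorin gene Sema3c was 4.93-fold higher (1.59 to 24.7). Vegfa, the main angiogenic growth factor gene, was at 568 against 532 CPM (ratio 1.07, 0.884 to 1.29). Without the mural-like sub-cluster Vegfa was 1.88-fold higher (1.42 to 2.55), Eng had a ratio of 1.01 (0.502 to 2.25), and the list's median was -0.17. Vegfa stayed uncalled in 6 of 11 settings, and it was also called higher without mural-like and mixed cells. Genes of tip cells and activated endothelium were 4 lower of 11 (median -0.97), among them Esm1 (7.07-fold, 3.72 to 14.0) and the placental growth factor gene Pgf (1.97-fold, 1.15 to 3.31). Once mural-like and mixed cells were left out, Pgf was higher and Angptl4, Adm, Esm1, Kdr, Cdh5, Vwf and Eng were not called.

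**Figure D3:**
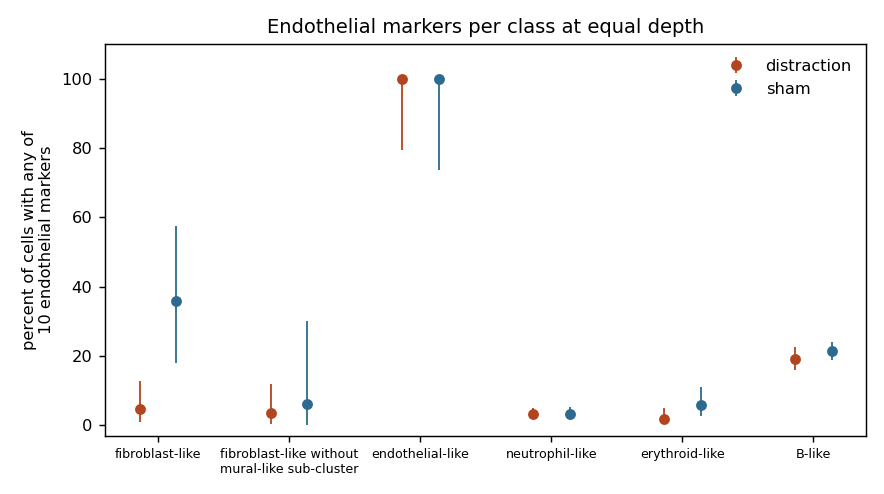
Percent of cells (vertical axis) with at least 1 UMI of any of 10 endothelial markers at 4000 UMIs per cell in each class and library, with exact 95% binomial intervals. Fibroblast-like cells stood at 4.62% against 36.0%, and at 3.45% against 6.25% without the mural-like sub-cluster, while neutrophil-like cells were at 3.21% and 3.13%.

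Neutrophil-like cells of the distraction library had more Spn, the sialophorin gene (1.78-fold, 1.61 to 1.98), Tuba4a (1.59-fold), Tm6sf1 (1.56-fold), Tspan2 (1.53-fold) and Papss1 (1.53-fold). They had less Fut7, the fucosyltransferase gene for selectin ligands (2.53-fold, 2.20 to 2.91), Gadd45b (2.13-fold), Gabbr1 (1.95-fold) and Sts (1.77-fold). Class II genes were 4 lower of 4 in this class (median -1.76), among them Cd74 at 11.1 against 49.7 CPM, far below its 562 and 771 CPM in B-like cells. The same 4 genes were lower in granulocyte progenitor-like (median -2.04) and erythroid-like cells (median -2.14). With a pseudocount of 10 CPM the medians were -1.06, -1.03 and -1.32, and a list minimum of 50 CPM gave no value in the neutrophil-like and progenitor-like classes. In these 3 classes the 4 genes reached at most 1.14% of the level of the class with most of them, below the 10% set against free RNA. The B marker Cd79b was lower alongside, at 10.2 against 39.7 CPM in neutrophil-like, 7.94 against 14.4 in progenitor-like and 3.78 against 24.7 in erythroid-like cells, so RNA of other cells was not separated from expression here.

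Monocyte-like cells had higher Retn (2.61-fold, 1.97 to 3.49), Akr1b1 (1.90-fold), Pdpn (1.71-fold), Dusp2 (1.70-fold) and the cholesterol exporter gene Abca1 (1.65-fold), and lower Cd93 (1.97-fold), RT1-A1 (1.89-fold), Rassf5 (1.83-fold), Gbp5 (1.80-fold) and Fyb1 (1.73-fold). In granulocyte progenitor-like cells the neutrophil defensin genes Defa11 (5.01-fold, 4.05 to 6.26) and Defa10 (3.22-fold) and Lbp (3.04-fold) were higher, and RT1-A1 (2.43-fold), Cd69 (2.20-fold) and Fcnb (2.16-fold) lower. Genes with at least 50 CPM in both libraries shifted by a median log2 ratio of -0.12 in that class. When each cell weighed the same, the log2 ratios of the named genes shrank to 0.17 for Defa11, 0.54 for Defa10, -0.05 for Lbp, -0.60 for RT1-A1, -0.50 for Cd69 and -0.48 for Fcnb. The class drew on different clusters, with the deeper cluster holding 145 of its 187 distraction cells and 78 of its 148 sham cells.

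Erythroid-like cells had higher Nfkbiz (2.29-fold, 1.92 to 2.73, with a log2 ratio of 0.28 when each cell weighed the same), Gata2 (2.08-fold) and Zfp691 (2.08-fold), and lower Fam111a (1.95-fold), Pcnt (1.85-fold) and Cyp1b1 (1.85-fold). In B-like cells Ckb, the brain-type creatine kinase gene, was 1.72-fold higher (1.60 to 1.84), with Psat1 and Rad18 at 1.44-fold each, under the 1.5-fold needed for a call, while Cd3g (2.39-fold, 2.11 to 2.71), Myadm (1.98-fold) and RT1-A1 (1.78-fold) were lower. In dendritic-like cells the elastase gene Mmp12 was 52.7-fold higher (14.2 to 441), Slpi 7.69-fold and the chemokine gene Xcl1 5.34-fold higher, and Mmp13 (79.4-fold, 13.8 to 3176), Ctsk (31.2-fold, 11.9 to 116) and Clec10a (23.6-fold, 6.19 to 201) were lower. Counts were 106 against 2 for Mmp12, 1 against 79 for Mmp13, 4 against 124 for Ctsk and 2 against 47 for Clec10a. Mmp13 was at 10.1% of its highest class, just over the limit set against free RNA. Mixed cells were not removed from the dendritic-like class, and the weight of single cells in these counts is not given. Of 15 inflammatory genes in dendritic-like cells 10 were lower and none higher (median -0.89), among them the monocyte chemokine gene Ccl2 (10.8-fold, 8.37 to 14.0) and Cxcl1 (3.43-fold, 3.13 to 3.77).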

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

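The checks of cells outside the filters were made after the depth of the libraries had been seen. Cells with 25% or more mitochondrial UMIs, which entered no comparison, were 16.8% of the deposited distraction cells (819 of 4889, 15.7 to 17.8) and 2.95% of the deposited sham cells (158 of 5351, 2.52 to 3.44), and the level above that of the control library is what drew attention to them. Among cells with at least 920 UMIs, the lowest depth in the sham table, the shares were 6.34% (272 of 4288) and 2.95%.

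Cells with under 500 UMIs were 7.42% of the deposited distraction cells (363 of 4889, 6.71 to 8.20) and 0 of 5351 sham cells, with an exact upper bound of 0.0689%.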

How the results depend on the processing

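The settings without mural-like cells, without mixed cells, without both, without each gene's highest cell, without the highest 2.5% of doublet scores and with 920 UMIs as the minimum were chosen after seeing the data, and the others before. No paired analysis was possible because each group has 1 library. For the shares, the 6 main fibroblast-like lists and the endothelial marker shares, 89 alternative values stayed within the counting interval, 61 moved beyond it in the same direction or to 0, and 4 reversed. For the other results 1719 stayed, 455 moved and 89 reversed. Over the settings of cells and clusters and the share among cells other than red cells, the neutrophil-like ratio ran from 1.80 to 2.21, and over cells and clusters the erythroid-like ratio ran from 1.44 to 1.73. Among cells other than B-like these ratios were 1.21 and 0.957, and over the settings they ran from 0.991 (every deposited cell kept, reversed) to 2.44 and from 0.796 to 2.02, with the upper ends from separate clustering. Depth limits the fibroblast-like values, since the 33 sham cells hold 266810 UMIs in all.

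With each library clustered on its own, the B-like ratio was 1.58 for the naming reason given with the shares, and the osteoblast-like ratio and the endothelial-like ratio (1.74 as reported) were 0, because the distraction stromal cells fell in 1 cluster that stayed unnamed. With every deposited cell kept, the ratios were 0.497 for B-like, 1.80 for neutrophil-like and 1.53 for fibroblast-like cells, and among stromal cells the fibroblast-like ratio was 1.56. The B-like ratio was 0.617 with called doublets kept and 0.620 at resolution 2.

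With called doublets kept, and in the same way at resolution 2, the fibroblast-like class held 62 and 20 cells. The median log2 ratios there were 0.14 for collagens and matrix, -0.54 for osteogenic genes, -0.17 for angiogenic ligands, -1.37 for endothelial identity, -0.75 for the BMP list and 0.79 for neutrophil granules. Medians that reversed were -0.0127 for collagen processing, 0.97 for inflammatory genes and 0.0700 for tissue repair macrophages. Genes that reversed were Adamts4 at 1.26, Cxcl12 at 0.13, Esm1 at 1.17, Junb at 0.29, Pgf at 0.52, Spp1 at 3.62 and Vcam1 at 1.21, and the log2 ratio of Eng in fibroblast-like cells was 0.0185. With called doublets kept, 6.25% of sham fibroblast-like cells held any endothelial marker. In that setting the endothelial-like class held 36 distraction and 30 sham cells, against 23 and 17 as reported. It held 34 and 28 with at least 1500 UMIs and stayed at 23 and 17 at resolution 2. Whether fibroblast-like cells moved to that class was not tested.

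With at least 1500 UMIs the medians were 0.14 for collagens and matrix, -0.55 for osteogenic genes, -0.17 for angiogenic ligands, -1.37 for endothelial identity, -0.77 for the BMP list and 0.79 for neutrophil granules, and they reversed to -0.0441 for collagen processing, 0.97 for inflammatory genes and 0.0643 for tissue repair macrophages. Adamts4 reversed to 1.253, Cxcl12 to 0.12, Esm1 to 1.17, Junb to 0.27, Pgf to 0.52, Spp1 to 3.62 and Vcam1 to 1.20, and the log2 ratio of Eng in fibroblast-like cells was 0.0129.

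Without the mural-like sub-cluster the medians were 0.14 for collagens and matrix, -0.17 for angiogenic ligands, -1.37 for endothelial identity and -0.77 for the BMP list, and they reversed to -0.0625 for collagen processing, 0.98 for inflammatory genes and 0.0729 for tissue repair macrophages. Adamts4 reversed to 1.29, Eng to 0.0179, Junb to 0.28, Pgf to 0.52, Spp1 to 4.00 and Vcam1 to 0.72, and 6.25% of sham cells held any endothelial marker. Of these genes only Adamts4 and Spp1 were called, both as higher.

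Without mixed cells the medians were 0.19 for collagens and matrix, -0.49 for osteogenic genes, -0.40 for angiogenic ligands, -0.99 for endothelial identity and -0.82 for the BMP list, and they reversed to -0.33 for neutrophil granules and 1.13 for tissue repair macrophages. Reversed genes were Arg1 at 2.20, Ccl3 at -0.79, Cdh5 at 1.48, Ltbp1 at -0.13, Mmp8 at -0.67, Parvb at 2.20, Pf4 at 3.56, Pla2g2a at 0.24, Pmaip1 at -1.01, S100a9 at -0.33, Spp1 at 2.95, Treml1 at 1.48, Vwf at 1.48 and Wif1 at 0.83, and the log2 ratio of Cd74 in fibroblast-like cells was -4.28. Of these genes only Spp1, as higher, and Cd74, as lower, were called. Arg1, Cdh5, Parvb, Treml1 and Vwf had so few counts left that the pseudocount sets their values. Cdh5 had 1 distraction count in the whole class. For S100a9, Mmp8 and neutrophil granules the setting takes out the cells that hold them by construction.

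Without mural-like and mixed cells the medians were -0.0824 for collagens and matrix (reversed), -0.46 for osteogenic genes, -0.0833 for angiogenic ligands, -0.54 for endothelial identity and -0.62 for the BMP list. Reversed medians were -0.13 for neutrophil granules, 0.0856 for inflammatory genes, 0.35 for contractile genes and 0.60 for tissue repair macrophages. Reversed genes were Adamts4 at 0.98, Ltbp1 at -0.13, Matn4 at 2.83, Mcam at 0.54, Mmp8 at -1.32, Myl9 at 1.27, Parvb at 2.34, Pf4 at 3.48, Pgf at 5.85, Pla2g2a at 3.19, Pmaip1 at -1.41, Spp1 at 3.74, Tpm1 at 0.0497, Vcam1 at 1.14 and Wif1 at 0.99, and the log2 ratio of Cd74 in fibroblast-like cells was -3.31. Of these genes only Pgf and Spp1 were called, both as higher. The log2 ratio of Junb in fibroblast-like cells was 0.0637 and the log2 ratio of Nkd2 in fibroblast-like cells was 0.0649. The share of cells with any endothelial marker was 0% in both libraries.

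Without each gene's highest cell the medians were 0.70 for collagens and matrix, -0.48 for osteogenic genes, -0.51 for endothelial identity, -0.77 for the BMP list and 0.78 for neutrophil granules, tissue repair macrophages reversed to 1.33, and Arg1 reversed to 1.09, Pf4 to 3.62, Spp1 to 2.52 and Vwf to 1.09. Of these genes only Spp1 was called, as higher. Arg1 and Vwf had so few counts left that the pseudocount sets their values. With cells thinned to 4000 UMIs, collagens and matrix were at 0.25, osteogenic genes at -0.95 and neutrophil granules at 2.60. With the mean of each cell's own CPM, collagens and matrix were at 0.33, osteogenic genes at -0.69, angiogenic ligands at -0.26, endothelial identity at -1.32 and the BMP list at -0.83, and the log2 ratio of Lbp in granulocyte progenitor-like cells reversed to -0.0541. Without the highest 2.5% of doublet scores, endothelial identity was at -3.55 and neutrophil granules at 0.91.

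With a list minimum of 50 CPM, endothelial identity was at -0.82, collagens and matrix in erythroid-like cells reversed to 0.30 (from -0.36), collagen processing in granulocyte progenitor-like cells to 0.0499 (from -0.42) and matrix degradation in monocyte-like cells to -0.29 (from 0.46), with fewer members by construction. A pseudocount of 10 CPM put endothelial identity at -1.11. The sham share with any endothelial marker was 16.0% from 2 UMIs and 16.1% when thinned to 2000 UMIs. Apart from naming, construction and single cells as stated, the cause was not tested.

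Some alternatives gave no value. Separate clustering gave no fibroblast-like, T or NK-like or megakaryocyte-like ratio and so no fibroblast-like genes, resolution 0.5 no osteoblast-like, dendritic-like or T or NK-like ratio, and every deposited cell kept no osteoblast-like ratio. The list minimum of 50 CPM left too few members for red cell genes in dendritic-like, endothelial-like, granulocyte progenitor-like and osteoblast-like cells, class II genes in neutrophil-like and granulocyte progenitor-like cells, angiogenic ligands in B-like, Wnt in endothelial-like, suture progenitors in macrophage-like, endothelial identity in osteoblast-like, and TGF-beta and osteoclast genes in monocyte-like cells. Equal weight per cluster could not be set against the reported value, because the fibroblast-like class is 1 cluster and 0 of its sub-clusters reach 20 cells in both libraries.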

Other observations

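The tests on shallow cells and on class I antigen processing were written before their values were seen, and all other tests below were chosen after the result was seen, with the reading of both RT1 tests and of the tests on marrow and on mural-like cells made stricter at that point and the test on fewer B-like cells replaced, after its first form had decided nothing and ratios of single classes had been seen.

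Small classes showed differences not described so far, with no check for the weight of single cells. Endothelial-like cells (23 distraction, 17 sham) had 7 of 17 inflammatory genes higher and 1 lower (median log2 ratio 0.63), among them the chemokine gene Ccl2 at 3750 against 573 CPM (6.54-fold, 5.18 to 8.37) and Il6 (3.17-fold, 2.09 to 4.98). The E-selectin gene Sele, which marks activated endothelium, was 2.40-fold higher (1.52 to 3.92) in these cells. Proliferation genes there were 3 lower of 15 (median -2.24), with Top2a at 1 against 19 counts (25.7-fold, 4.08 to 1066).

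Osteoblast-like cells (13 and 26) had 8 of 21 collagen and matrix genes higher and 0 lower (median 0.54), among them Thbs2 (3.32-fold, 2.13 to 5.23). Of these 8 genes 6 stayed below 10% of their level in the class with most of them, such as Postn at 8.10% (388 against 17.6 CPM) and Col3a1 at 9.91%, so RNA of fibroblast-like cells was not separated from expression here. The bone growth factor gene Bmp2 was 3.18-fold lower (2.63 to 3.87) in them. Macrophage-like cells (31 and 26) had higher Ccl24, an eosinophil chemokine gene (202 against 1 count, 120-fold, 21.3 to 4767), Spp1 (4.90-fold, 3.11 to 8.11) and Arg1 (18 counts against 0, at least 3.57-fold, exact lower bound 2.61), and 4 of 8 class II genes lower, among them Cd74 (2.11-fold, 1.79 to 2.48).

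The B-like share was lower in the distraction library. Shallow cells called in that library alone are argued against, since the ratio was 0.599 (0.557 to 0.643) with at least 1500 UMIs in both. Neutrophil-like cells per B-like cell were 3.66 times as many (3.27 to 4.08), and 3.35 to 3.66 times over the settings with both libraries clustered together. That argues against less marrow of the same make-up as the whole cause. The ratio restates the shares already given and does not measure the marrow dissected, so the amount of marrow stays open. Whether fewer B-like cells are the only difference was not decided. Neutrophil-like cells per erythroid-, monocyte- or progenitor-like cell were 1.32 times as many (1.15 to 1.51) and 1.18 to 1.43 times over all settings. That ratio was chosen after ratios of single classes had been seen. Among those, neutrophil-like per erythroid-like cells had an interval that included 1 with at least 1500 UMIs. With every deposited cell kept, the ratios among cells other than B-like were 0.991 for neutrophil-like and 0.796 for erythroid-like cells. Handling of the suspension, differences between animals and the distraction itself stay open, untested with 1 library per group.

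Endothelial markers were found in fewer fibroblast-like cells of the distraction library. Free RNA as the source of the sham share of 36.0% (18.0 to 57.5) was not settled. Sham neutrophil-like cells held the markers at 3.13% (1.62 to 5.40), below that interval, but sham B-like cells at 21.4%, within it. The B-like cells held mainly Tie1 (161 of 997 cells), with Cdh5, Emcn and Kdr, which 9, 8 and 11 of 12 sham endothelial-like cells held, in 0 of 997. Sham fibroblast-like cells held Esam in 5 of 25, Tie1 and Kdr in 3 each, Egfl7 in 2, Cdh5 in 1 and Emcn in 0. The share of mural-like and mixed cells in the class cannot be told apart from a difference within fibroblast-like cells, since without them 0% of sham cells (0 of 13) held a marker, but the upper bound of 24.7% lies above 18.0%, the lower bound for all sham fibroblast-like cells. Removal of mixed cells alone left 1 of 48 against 5 of 20 cells (2.08% in the distraction library). Removal of the mural-like sub-cluster alone left 2 of 58 against 1 of 16, so the sham cells with a marker lay mainly in that sub-cluster. The mural-like sub-cluster also had the highest summed level of the markers (438 CPM, against 81.2 and 17.3). Whether strain alters its share, or the markers within it, was not tested.

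Among the RT1 class I genes, the rat's MHC class I genes, RT1-A1 had a ratio below 1 in 8 of 8 classes (median log2 ratio -0.87) and was called lower in 6, not in erythroid-like or macrophage-like cells. A shift of reads between these genes is argued against, since their summed counts had a median of -0.45 (-1.24 to -0.26 over the classes). A general shift of class I antigen processing cannot be told apart, since 6 genes of that pathway had a median of -0.12 with members on both sides, from Tap1 at -0.39 to Psmb8 at 0.18. An allele that differs from the reference may account for the pattern and cannot be told apart from a change in expression, because the deposited counts carry no sequence. Beta-2-microglobulin (B2m), the shared light chain, had a median of -0.01.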
